A study of Mus musculus with 4 samples.

How the data were processed

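RNA was measured in 4 samples of EpCAM-positive cells from mouse oral tumours, 2 sorted as Tomato-positive and 2 as Tomato-negative, 24 hours after tamoxifen. Per the labels' protocols, RNA was isolated with a column kit for small samples and made into libraries with a KAPA kit. Per the submitters' processing notes, TopHat, Cuffdiff and the mouse build mm9 were used. Versions, strand settings and annotation are not given in the sources used here.

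Per the file headers, the authors' deposited table holds 1 FPKM value per gene for each of the 2 fractions, as group values that join both samples. FPKM divides fragments by transcript length and by the library total, so it depends on the other genes in the library and is inflated for short transcripts. MicroRNA rows, 686 in number, held 35.4% of the FPKM sum in Tomato-negative and 37.2% in Tomato-positive cells. The deposited log2 fold, the test statistic (a score), the p-value and the q-value are the authors' own, per the file headers. No per-sample values were used here, so no SD, n or leave-one-out value is given, and the depth per sample is unknown. The choices that needed values per sample were therefore not made, and the authors' q-values stood as the main test, as fixed before the data were examined.

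The table holds 37574 Ensembl genes. Of these 16219 had the status OK, 21023 were not tested, 330 had too little data and 2 had too many fragments. The authors' lowest deposited p-value was 5e-05, shared by 2004 genes, with a q-value of 0.000405. The test statistic was not used. A spreadsheet error stood in 2111 cells of the log2 fold, so log2 folds were computed again from the FPKM values. They differed by more than 0.01 from the deposited log2 for 3 of 16010 tested genes with both values. A spreadsheet had turned 25 gene symbols into dates, and all 25 were named again by Ensembl ID from a GENCODE table. Coordinates are mm9 as deposited, and 4523 tested genes share a locus with another gene, since overlapping genes were joined. Reads of near-identical paralogs, such as Krt6a and Krt6b, the alpha globins, and the Lce and Sprr2 families, can be divided between copies, so their separate values are uncertain.

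Directions are Tomato-positive over Tomato-negative. Genes with q below 0.05 were counted as called. The genes named were fixed before the data were examined: Bmi1 and Epcam; the 12 largest log2 folds in each direction among called genes with at least 5 FPKM in the higher fraction and above 0.1 in the other, leaving out predicted, clone and small RNA symbols; all members of the fixed lists; the 5 called genes with the highest mean FPKM of both fractions in each direction; and the 3 highest called genes listed at 0 in the other fraction.

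The 47 gene lists were also fixed before the data were examined. Each list with at least 3 tested members was compared with all other tested genes by a two-sided Fisher's exact test of called members, for higher and lower calls, with Benjamini-Hochberg adjustment over 88 tests. Another 3 lists had too few tested members. Where a symbol stood in several tested rows, the row with the highest mean FPKM was kept, a rule set after the table was seen, which left 16066 symbols. The count adjusted over the list alone applies the Benjamini-Hochberg adjustment to the deposited p-values of the list's members. A list's median log2 of (FPKM + 1) was set against 10000 random lists matched in 20 bins of mean log2 expression, as a description. Intervals of list medians are 95% bootstrap intervals over members from 2000 resamples. A further 18 gene families were defined by symbol after the data were seen. A longer list of granulocyte genes was drawn up after its genes had been seen to rise. It was run once, with most members higher, and set aside for that reason. The neutrophil list fixed beforehand was used in its place.

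The list tests were tested on simulated data made by shuffling outcomes over the 16066 symbols within expression bins, with 10 planted lists of 20 genes. All 5 lists planted at a fold of 2, with calls in 50% of members, and all 5 at a fold of 4, with calls in 80%, were recovered. The calls were set by these rates, not by the fold, so recovery does not show that a given fold is detected. Shorter lists were not planted. Of 88 tests on shuffled lists 0 passed. Shuffling removes any joint movement of list members, so this gives no error rate for lists whose genes move together. In an earlier run with calls in 50% of members at both folds, 2 of the 5 lists at a fold of 4, which by chance drew few calls, did not pass, and the rate was then raised. Alternatives to the q threshold, filters on FPKM, a minimum fold, centring, and the pseudocount were computed, and their effect is given in the closing section. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.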

Results

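Oral tumours came from mice treated for 26 weeks with 4NQO, a chemical carcinogen that forms DNA adducts. The mice carried a tamoxifen-inducible Cre under the control of Bmi1 and a Cre-dependent tdTomato reporter, so that a tamoxifen pulse marked cells in which the Bmi1 promoter was active. Tumour cells were collected 24 hours after tamoxifen, and cells positive for the epithelial surface protein EpCAM were sorted into a Tomato-positive and a Tomato-negative fraction. RNA was sequenced from 2 samples of each fraction, 4 samples in all. The comparison asked how the transcripts of Bmi1-marked tumour epithelial cells differed from those of the unmarked EpCAM-positive cells of the tumours. The values are the authors' group values in FPKM, fragments scaled by transcript length and library total, with 1 value per gene and fraction. They therefore carry no SD, and the depth of each sample is unknown. All FPKM and q-values given are from the authors' deposited table, and log2 folds were computed from its FPKM values. In that table the spread between samples can enter only through the p-value and q-value. The labels do not say whether the 2 samples of a fraction came from separate animals, so the p-values cannot be read as a measure of spread between animals.

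Bmi1 transcripts, which encode a subunit of Polycomb repressive complex 1, were higher in the fraction sorted for the Bmi1-driven label. Bmi1 (chromosome 2, 18598644 to 18608256, mm9) stood at 3.11 FPKM in Tomato-negative and 7.03 FPKM in Tomato-positive cells. In the authors' deposited table this was a log2 fold of 1.18 with q = 0.00109. Epcam (chromosome 17, 88035318 to 88050446), the surface protein both fractions were sorted on, was present in both and rose from 25.1 to 46.4 FPKM, a log2 fold of 0.89 in the authors' deposited table with q = 0.000405. That q is the lowest the table holds.

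The Tomato-positive fraction had higher transcripts of basal and wound keratins, chemokines and matrix-remodelling genes, and lower transcripts of cornification, gland, muscle and interferon genes. Whether RNA of other cells, such as neutrophils or muscle, contributed to these differences stays open. Of 16219 genes tested, 4412 were called at q below 0.05 in the authors' deposited table, 2106 higher and 2306 lower in Tomato-positive cells. At least 2-fold differences were called for 1153 higher and 1569 lower genes, and at least 4-fold differences for 348 and 670. Among called genes with at least 5 FPKM in the higher fraction and above 0.1 in the other, leaving out predicted, clone and small RNA symbols, the neutrophil-attracting chemokine Cxcl2 had the largest rise, from 0.739 to 112 FPKM. It was followed by Trem1, a receptor of myeloid cells, from 0.110 to 7.60 FPKM, and Lrat, which esterifies retinol, from 0.183 to 12.5 FPKM. The chromatin protein gene Hmga2 rose from 0.133 to 9.08 FPKM, the natriuretic peptide gene Nppb from 0.699 to 47.2 FPKM and Slitrk5 from 0.121 to 8.12 FPKM. Il24 went from 0.201 to 12.9 FPKM and Cxcl3 from 0.346 to 20.9 FPKM. Irg1, which makes itaconate, rose from 0.664 to 33.2 FPKM, Ccl3 from 1.10 to 54.7 FPKM, Ccl4 from 0.949 to 45.7 FPKM and Ajap1 from 0.359 to 15.3 FPKM. The log2 folds of these 12 genes lay between 5.42 for Ajap1 and 7.25 for Cxcl2 in the authors' deposited table.

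The 12 largest falls under the same criteria were led by Cyp2a5, a cytochrome P450, from 61.6 to 0.505 FPKM, a log2 fold of -6.93 in the authors' deposited table. The muscle genes Car3 (19.4 to 0.218 FPKM), Apobec2 (21.4 to 0.283 FPKM), Art1 (16.7 to 0.314 FPKM), Ckm (178 to 4.79 FPKM), Actc1 (9.85 to 0.321 FPKM) and Casq1 (10.3 to 0.341 FPKM) fell as well. Tff2, a secreted mucosal peptide, fell from 110.3 to 2.30 FPKM and Gp2 from 10.7 to 0.260 FPKM. Penk went from 21.7 to 0.646 FPKM, the class II pseudogene H2-Ea-ps from 84.2 to 2.75 FPKM and Fmo9 from 9.82 to 0.329 FPKM. By mean FPKM of both fractions, the 5 most abundant genes called higher were Krt14, Krt16, the short predicted gene Gm14287 (3785 to 5705 FPKM), Krt17 and Anxa1, an inhibitor of phospholipase A2, from 1594 to 5537 FPKM. By the same mean, the 5 most abundant called lower were Krtdap (24504 to 14345 FPKM), Slpi, the metallothionein Mt4 (13279 to 3579 FPKM), Lor and Fam25c (7744 to 2533 FPKM). A further 17 genes were called higher from 0 FPKM in Tomato-negative cells. Their highest values were 72.2 FPKM for n-R5s193, 59.6 FPKM for Snord118 and 54.5 FPKM for n-R5s1, all short RNAs. Another 43 were called lower and listed at 0 in Tomato-positive cells, led by Gkn2 at 28.1 FPKM, Dcpp1 at 12.7 FPKM and Dcpp2 at 9.59 FPKM in Tomato-negative cells.

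**Figure D1:**
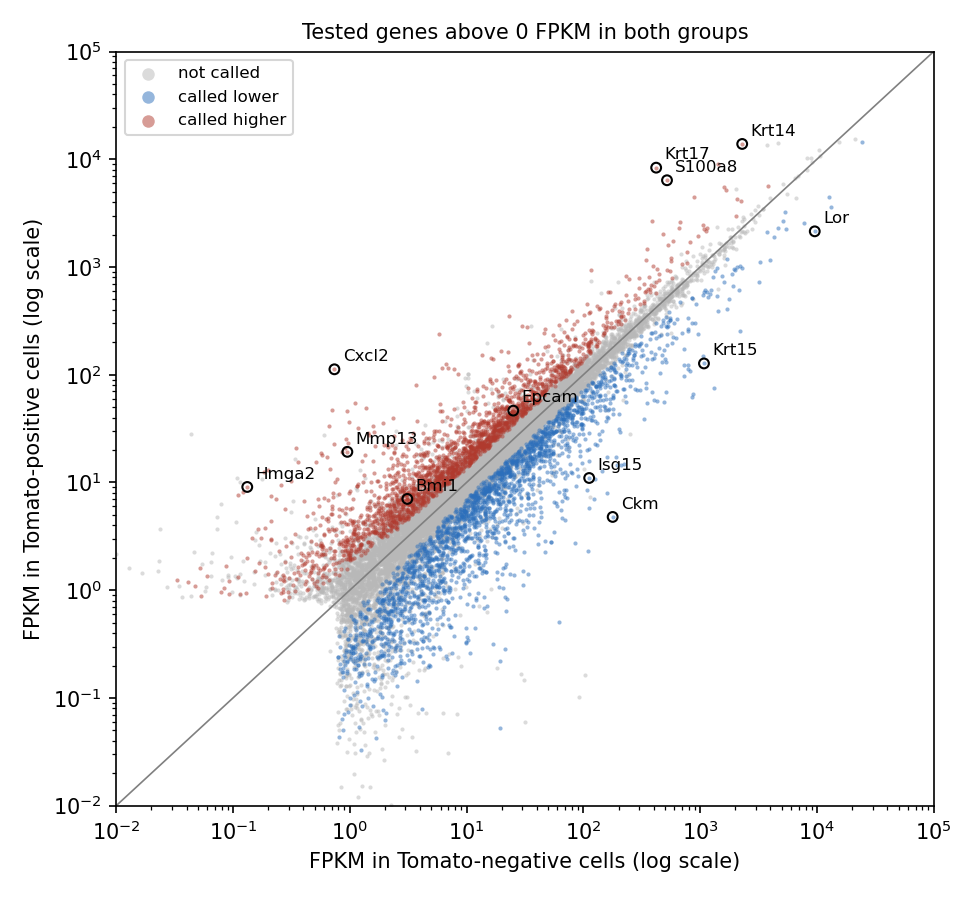
FPKM in Tomato-negative (x axis) against Tomato-positive cells (y axis), both on log scales, for the 16008 tested genes drawn, coloured by the authors' call at q below 0.05. Points are the authors' group values and the line marks equal values; Krt14, Krt17, S100a8, Cxcl2, Mmp13 and Hmga2 lie above it, and Lor, Krt15, Isg15 and Ckm below it.

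Basal keratinocyte genes, among them keratins and genes that tie the cell to the basement membrane, rose in 12 of 15 members. Krt14 increased from 2292 to 13864 FPKM and Krt5 from 1670.5 to 5176 FPKM. The integrin chains Itga6 (46.6 to 265 FPKM) and Itgb4 (28.9 to 106 FPKM), which form the hemidesmosome receptor for laminin, rose with Lama3 (8.45 to 101 FPKM) and Col17a1 (82.6 to 294 FPKM). Trp63, the transcription factor of stratified epithelia, rose from 66.0 to 109.9 FPKM. Krt15 was the member that fell, from 1078 to 127 FPKM. Bcam (53.4 and 50.1 FPKM) and Egfr (13.1 and 14.3 FPKM) did not pass the test. The enrichment of higher calls had an adjusted p of 8.3e-08 by Fisher's exact test, and the counts were also 12 and 1 adjusted over the list alone.

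Wound-activated keratins and alarmins rose in 7 of 11 members (9 adjusted over the list alone, beside 1 lower), with Fisher's exact adjusted p = 0.00083. Krt17 went from 420.3 to 8352 FPKM and Krt16 from 1410.4 to 9015 FPKM. The calcium-binding alarmins S100a8 (520.4 to 6383 FPKM) and S100a9 (882 to 4506 FPKM) rose, as did the interleukin-1 receptor antagonist Il1rn (71.0 to 325 FPKM) and the defensin Defb14 (482 to 2014 FPKM). S100a8 and S100a9 also stand in the list of neutrophil markers, which rose in 5 of 7 tested members and fell in 1. Slpi, a protease inhibitor, fell from 12696 to 4421 FPKM. Krt6a was listed at 3754 and 13654 FPKM with q = 0.109 in the authors' deposited table, and Krt6b at 4680.1 and 14018 FPKM with q = 0.142. These near-identical keratins can share reads, and their separate values are uncertain.

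Keratinocyte differentiation genes fell in 17 of 31 tested members and rose in 5 (18 and 5 adjusted over the list alone), with Fisher's exact adjusted p = 1.44e-06 for lower calls. Loricrin (Lor), the main protein of the cornified envelope, fell from 9582 to 2142 FPKM. Rptn (1701 to 406 FPKM), Tgm3 (1908 to 661 FPKM), Krt1 (627 to 219.5 FPKM) and Krt10 (787 to 336 FPKM) fell too. The members that rose were Sprr2d (117 to 929.5 FPKM), Sprr2h (80.4 to 392 FPKM), Sprr1a (2063 to 4315 FPKM), Krt76 (17.1 to 53.6 FPKM) and Dsc2 (114 to 199.5 FPKM). Ivl was listed at 9.54 and 6.57 FPKM and Tgm1 at 256 and 277 FPKM, neither past the test. Krt4 and Krt13, keratins of the oral suprabasal layers, were listed at 0 in Tomato-negative cells and at 4320 and 15058 FPKM in Tomato-positive cells, but had a status of too many fragments and were not tested.

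Simple epithelial and gland genes fell in 10 of 13 members and rose in 1, also when adjusted over the list alone, with Fisher's exact adjusted p = 5.3e-06. The mucin Muc5b fell from 112 to 5.76 FPKM, lactoferrin (Ltf) from 40.9 to 2.67 FPKM, Krt19 from 21.9 to 1.77 FPKM and Krt7 from 10.2 to 0.371 FPKM. Krt18 rose from 5.67 to 9.92 FPKM. In the same comparison skeletal muscle markers fell in 12 of 14 (median -3.14) and fibroblast and pericyte markers in 14 of 16 (median -1.13). Neither list had a member called higher, while endothelial markers were higher in 5 of 12 and lower in 1.

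Invasion and matrix protease genes rose in 17 of 21 members, with Fisher's exact adjusted p = 9.41e-11. The collagenase Mmp13 rose from 0.954 to 19.2 FPKM. The activin subunit Inhba went from 1.43 to 28.9 FPKM. Mmp2 fell from 33.3 to 7.78 FPKM. Mmp10 was listed at 0.0438 and 28.4 FPKM and did not pass, at q = 0.298 in the authors' deposited table. Counts adjusted over the list alone were 17 and 1. TGF-beta response genes, some of which also stand in other lists, rose in 11 of 16 members (12 adjusted over the list alone, beside 1 lower) with Fisher's exact adjusted p = 3.81e-06. Tgfb1 rose from 6.81 to 20.7 FPKM and Smad7 from 2.92 to 7.75 FPKM, and Id2 fell from 24.4 to 15.1 FPKM.

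Genes of the epithelial-mesenchymal transition did not move together: 3 of 13 rose (4 adjusted over the list alone), 2 fell (5), and the adjusted p for higher calls was 0.466 by Fisher's exact test. The list median was -0.50, opposite in sign to the larger count. Snai2, a repressor of E-cadherin, rose from 14.6 to 42.7 FPKM, Tgfbi from 32.8 to 139.6 FPKM and Sparc from 77.0 to 109 FPKM. Fn1 fell from 12.4 to 6.32 FPKM and Twist2 from 2.91 to 0.668 FPKM. Vim (182 and 127 FPKM) and Zeb1 (2.53 and 1.17 FPKM) did not pass. Fibroblast and pericyte markers, cells that also express mesenchymal genes, fell in the same comparison in 14 of 16 members, with a list median of -1.13. ERBB and growth factor genes rose in 8 of 16 members and fell in 3 (8 and 3 adjusted over the list alone), with Fisher's exact adjusted p = 0.0024 for higher calls. Apart from the receptor Met, those that rose were ligands, such as Epgn from 23.0 to 353 FPKM, Nrg1 from 1.47 to 27.3 FPKM and Areg from 3.75 to 37.1 FPKM. The receptors Erbb2 (29.0 to 16.6 FPKM), Erbb3 (16.2 to 9.20 FPKM) and Fgfr3 (17.3 to 9.31 FPKM) fell, and Met rose.

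G2 and M phase genes rose in 20 of 24 members and fell in 0, with Fisher's exact adjusted p = 1.09e-12. Cdk1, the kinase that drives mitotic entry, rose to 64.3 FPKM, Ttk from 2.78 to 8.95 FPKM, Aurka from 4.27 to 11.8 FPKM and Mki67 from 10.7 to 24.2 FPKM. S phase genes were higher in 5 of 24, with an adjusted p of 0.466 by Fisher's exact test. Mcm5 rose from 12.2 to 23.0 FPKM and Ccne1 from 5.62 to 14.4 FPKM, while Pcna (61.9 and 71.0 FPKM) and Mcm6 (14.4 and 12.6 FPKM) did not pass. Adjusted over the list alone, 21 G2 and M phase genes and 5 S phase genes were higher. Whether the lists differed from each other was not tested. Among 12 genes for inhibitors of cyclin-dependent kinases and quiescence, Cdkn2a rose from 42.9 to 90.6 FPKM and Cdkn2c fell from 23.3 to 9.08 FPKM. The other 10 did not pass, Cdkn1a at 211 and 173 FPKM among them, and the counts were also 1 and 1 adjusted over the list alone. Of 17 p53 target genes 2 rose, Pmaip1 from 4.35 to 17.8 FPKM and Phlda3 from 125 to 215 FPKM, and Trp53inp1 fell, with the same counts adjusted over the list alone. Both lists had an adjusted p of 1.0 for higher calls by Fisher's exact test.

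Hypoxia and glycolysis genes rose in 16 of 19 members (17 adjusted over the list alone) and fell in 0, with Fisher's exact adjusted p = 1e-10. Ndrg1 rose from 29.6 to 286 FPKM, the carbonic anhydrase Car9 from 1.51 to 10.1 FPKM, Bnip3 from 16.0 to 87.2 FPKM and the glucose transporter Slc2a1 from 64.3 to 203 FPKM. Aldoa (611 and 817 FPKM) and Hk2 (40.5 and 57.2 FPKM) did not pass. None of the 20 oxidative phosphorylation genes was called by the authors' q from Cuffdiff or adjusted over the list alone, for example Atp5b at 1102 and 1032 FPKM, with 1 higher at an unadjusted p below 0.05. The adjusted p was 0.269 by Fisher's exact test in either direction, which concerns only the number of calls. The list median was slightly lower, at -0.19 (interval -0.27 to -0.13) and percentile 1.53 of the matched random lists. NRF2 and detoxification genes went both ways, with 3 of 20 higher and 7 lower and an adjusted p of 0.0682 for lower calls by Fisher's exact test. Aldh3a1 fell from 2205 to 253 FPKM and Gstm1 from 726 to 175 FPKM, while Gclm rose from 157 to 337 FPKM. The counts were 3 and 10 adjusted over the list alone. Drug efflux transporters were lower in 2 of 10, Abcc4 (9.82 to 4.71 FPKM) and Abcc3 (43.8 to 25.3 FPKM), with an adjusted p of 0.885 by Fisher's exact test. Unfolded protein response genes were higher in 4 of 14, such as Asns from 45.7 to 71.3 FPKM, with an adjusted p of 0.269 by Fisher's exact test. Both counts were the same adjusted over the list alone.

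Inflammatory cytokines and chemokines rose in 12 of 20 members, with Fisher's exact adjusted p = 8.1e-06. The interleukins Il1b (5.78 to 240.1 FPKM) and Il1a (6.78 to 40.2 FPKM) rose with Cxcl1 (0.728 to 22.5 FPKM) and Tnf (0.712 to 7.35 FPKM). Ccl5 fell from 13.1 to 4.27 FPKM and Cxcl10, an interferon-induced chemokine, from 14.9 to 6.96 FPKM. Counts of 12 and 2 also held adjusted over the list alone. Neutrophil markers, which include S100a8 and S100a9, rose in 5 of 7 tested members in the same comparison, with Fisher's exact adjusted p = 0.0035. Csf3r rose from 0.637 to 17.1 FPKM and Retnlg from 0.856 to 19.2 FPKM, and Il1r2 fell from 180.3 to 43.6 FPKM. Counts adjusted over the list alone were 5 and 1. AP-1 genes were higher in 3 of 11 and lower in 1, also when adjusted over the list alone, with an adjusted p of 0.373 by Fisher's exact test. Fosl1 rose from 0.905 to 20.7 FPKM, Atf3 from 1.48 to 5.55 FPKM and Junb from 109 to 193 FPKM, Jun fell from 47.7 to 27.1 FPKM, and Fos, at 19.6 and 26.1 FPKM, did not pass. Immediate early and dissociation stress genes, which can respond to tissue digestion, were higher in 5 of 20 and lower in 2, with an adjusted p of 0.376 by Fisher's exact test. Nr4a1 rose from 2.66 to 11.5 FPKM, and Egr1 (17.8 and 16.8 FPKM) and Hspa1b (85.8 and 91.2 FPKM) did not pass. The counts were 5 and 2 adjusted over the list alone.

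Interferon response genes fell in 17 of 19 members, with Fisher's exact adjusted p = 2.34e-11. Ifit1 fell from 23.6 to 1.42 FPKM, Isg15 from 112 to 11.0 FPKM and Oasl2 from 41.8 to 4.30 FPKM. Mx1 (2.19 and 0.627 FPKM) and Rsad2 (3.58 and 2.25 FPKM) did not pass, and 18 were lower adjusted over the list alone. Antigen presentation genes fell in 13 of 14 members, with Fisher's exact adjusted p = 1.91e-09. The class II invariant chain Cd74 fell from 303 to 72.5 FPKM, the peptide transporter Tap1 from 41.9 to 9.39 FPKM, the immunoproteasome subunit Psmb8 from 33.8 to 7.36 FPKM and B2m from 1973 to 930.1 FPKM. All 14 were lower adjusted over the list alone. Macrophage and dendritic cell markers also fell in 7 of 14 members and rose in 1, with Fisher's exact adjusted p = 0.00853. The complement genes C1qa (72.4 to 11.7 FPKM) and C1qc (43.7 to 7.19 FPKM) and Lyz2 (164 to 47.1 FPKM) fell, and Cd14 rose from 5.91 to 53.1 FPKM. There were 8 lower and 1 higher adjusted over the list alone. Immune checkpoint genes were higher in 3 of 8 and lower in 1, with an adjusted p of 0.233 by Fisher's exact test. Cd80 rose from 3.99 to 18.3 FPKM, Cd276 from 2.51 to 9.16 FPKM and Nt5e from 11.1 to 16.0 FPKM, Lgals9 fell from 36.7 to 19.6 FPKM, and Cd274 did not pass. Adjusted over the list alone, 4 were higher and 1 lower.

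**Figure D2:**
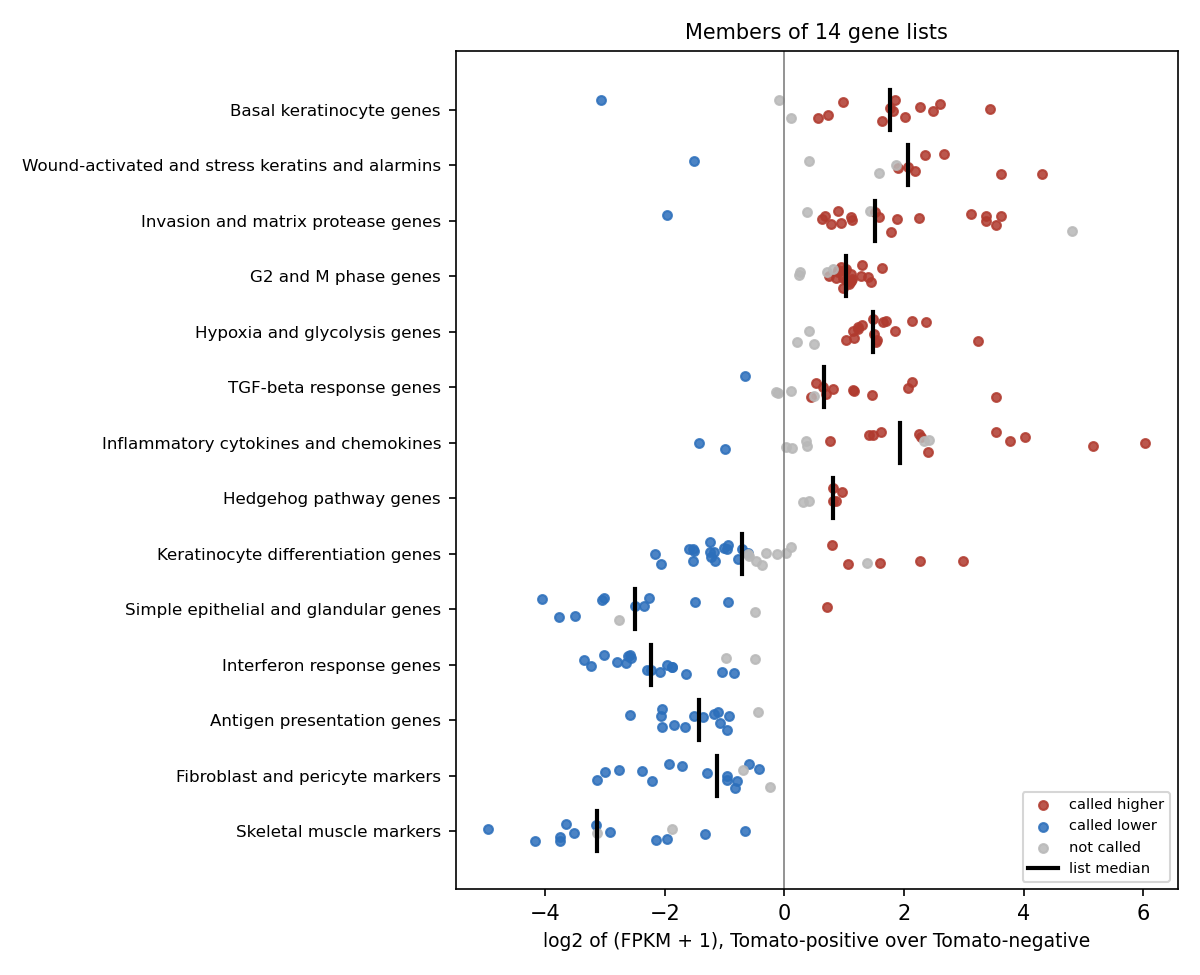
Each point is a tested member of 1 of 14 gene lists, placed by the log2 of (FPKM + 1) in Tomato-positive over Tomato-negative cells (x axis) and coloured by the authors' call at q below 0.05; vertical spread within a list is for display. Black bars are list medians, from -3.14 for skeletal muscle markers to 2.06 for wound-activated keratins and alarmins.

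Polycomb genes split, with 6 of 25 higher and 7 lower and an adjusted p of 0.233 for lower calls by Fisher's exact test. Apart from Bmi1, Jarid2 rose from 7.31 to 22.8 FPKM and Suz12, both of repressive complex 2, from 14.2 to 23.8 FPKM. The chromodomain genes Cbx8 (71.9 to 23.4 FPKM) and Cbx7 (4.67 to 1.20 FPKM) fell, and the methyltransferase Ezh2, at 11.1 and 11.7 FPKM, did not pass. Of 11 tested Hox genes, which Polycomb complexes repress in many tissues, 5 fell and 0 rose, with an adjusted p of 0.057 by Fisher's exact test. With at least 2-fold calls the same test gave an adjusted p of 0.0107, and with FPKM of at least 1 in either fraction an adjusted p of 0.0212. Hoxc4 fell from 22.5 to 3.42 FPKM, Hoxc6 from 14.8 to 3.54 FPKM and Hoxc8 from 25.1 to 8.92 FPKM. Adjusted over the list alone, 6 Hox genes were lower, and the Polycomb counts were again 6 and 7. Stem cell markers were higher in 4 of 16 and lower in 6, with an adjusted p of 0.069 for lower calls by Fisher's exact test. Cd44 (75.0 to 141 FPKM), Sox9 (1.73 to 10.2 FPKM), Procr (34.1 to 109.7 FPKM) and Aldh1a3 (2.94 to 14.6 FPKM) rose. Aldh1a1 (65.8 to 6.77 FPKM), Sox2 (53.2 to 21.7 FPKM) and Igfbp5 (26.3 to 4.09 FPKM) fell, and Myc (32.7 and 31.5 FPKM) and Klf4 (307 and 248 FPKM) did not pass. Counts adjusted over the list alone were 5 and 6.

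Hedgehog pathway genes rose in 4 of 6 tested members, with Fisher's exact adjusted p = 0.0172. Smo, the transducer of the pathway, went from 14.1 to 28.2 FPKM, Sufu from 4.40 to 8.87 FPKM, Gli2 from 0.481 to 1.61 FPKM and Gli3 from 0.918 to 2.37 FPKM. The pathway target Gli1 (0.545 and 0.915 FPKM) did not pass, nor did Ptch1 (3.02 and 4.37 FPKM). Members were counted whatever their role in the pathway, so the test does not show pathway activity. Notch pathway genes were higher in 2 of 10 and lower in 3, with an adjusted p of 0.373 for lower calls by Fisher's exact test. The receptors Notch1 (34.0 to 13.7 FPKM), Notch2 (11.4 to 6.54 FPKM) and Notch3 (14.2 to 8.77 FPKM) fell, and Jag2 and Lfng (7.21 to 14.7 FPKM) rose. WNT target genes were higher in 2 of 10 and lower in 2, with an adjusted p of 0.885 by Fisher's exact test. Ccnd1 rose from 44.8 to 67.7 FPKM, Nkd1 fell from 2.18 to 0.338 FPKM, and Axin2 stood at 2.89 and 2.95 FPKM without passing. For these 3 lists the counts were the same adjusted over the list alone.

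Markers of other cell types did not move in 1 direction. Fibroblast and pericyte markers fell in 14 of 16 members, with Fisher's exact adjusted p = 1.91e-09, such as Dcn from 406 to 58.5 FPKM and Col3a1 from 38.5 to 6.55 FPKM. Skeletal muscle markers fell in 12 of 14, with Fisher's exact adjusted p = 6.14e-08, such as Mylpf from 849 to 61.6 FPKM. Mast cell markers fell in 4 of 7 with Fisher's exact adjusted p = 0.0471, among them Mcpt4 from 7.45 to 1.39 FPKM, while Hdc, which neutrophils also express, rose from 0.562 to 18.6 FPKM. Erythroid markers rose in 5 of 5, with Fisher's exact adjusted p = 0.000258, the globin Hbb-b1 from 656 to 2283 FPKM and Alas2 from 6.88 to 21.7 FPKM. Endothelial markers were higher in 5 of 12 and lower in 1, with an adjusted p of 0.057 by Fisher's exact test. Cdh5 rose from 2.16 to 6.13 FPKM and Cldn5 fell from 4.43 to 0.809 FPKM. Pan-leukocyte markers were higher in 2 of 10 and lower in 3, with an adjusted p of 0.373 for lower calls by Fisher's exact test, and Ptprc, at 3.42 and 4.93 FPKM, did not pass. T and NK cell markers were lower in 3 of 11, such as Cd2 from 3.53 to 0.510 FPKM, with an adjusted p of 0.43 by Fisher's exact test. Langerhans cell markers, 5 of which stand in other lists beside Epcam from the sort, were lower in 4 of 8 with an adjusted p of 0.069 by Fisher's exact test. That p was 0.0189 with at least 2-fold calls and 0.0696 with FPKM of at least 1, by the exact test. Cd207, the marker most specific to these cells, stood at 4.94 and 3.14 FPKM without passing. None of the 4 melanocyte and Schwann cell genes tested was called, with 1 lower at an unadjusted p below 0.05 and an adjusted p of 1.0 by Fisher's exact test. Igj, the B cell gene tested, fell from 24.9 to 3.03 FPKM, and both tested genes of the Merkel and taste cell list, Pou2f3 (3.43 to 0.970 FPKM) and Dclk1 (0.910 to 0.447 FPKM), fell. Adjusted over the list alone, the counts rose to 13 lower muscle, 7 lower T and NK cell, 5 lower mast cell and 5 lower Langerhans cell markers, and to 3 higher and 4 lower pan-leukocyte markers. Those of fibroblasts, erythroid, endothelial, melanocyte, B and Merkel cells were the same.

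Among 24 ribosomal protein genes 1 was called, Rps2, which rose from 448 to 761 FPKM, and the adjusted p was 0.627 by Fisher's exact test. Housekeeping genes were higher in 3 of 14, Gapdh (80.8 to 190.0 FPKM), Pgk1 (61.5 to 173 FPKM) and Gusb (5.44 to 8.62 FPKM), and B2m was lower, with an adjusted p of 0.675 by Fisher's exact test. Tbp (15.3 and 13.7 FPKM) and Tfrc (47.7 and 47.7 FPKM) did not pass. Of 8 nuclear and long non-coding RNAs, H19 fell from 69.5 to 7.38 FPKM and Malat1 from 895 to 300.4 FPKM, with an adjusted p of 0.588 by Fisher's exact test. Adjusted over the list alone, 5 housekeeping genes were higher, 3 non-coding RNAs lower, and the ribosomal count was the same. The Y-linked genes Ddx3y (18.1 and 20.8 FPKM) and Eif2s3y (60.6 and 45.7 FPKM) were present in both fractions, Xist stood at 0.324 and 0.347 FPKM, and none of the 4 tested sex-linked genes was called, with 0 at an unadjusted p below 0.05 and an adjusted p of 1.0 by Fisher's exact test. Mitochondrially encoded genes were not analysed here. List medians and means differed in sign for 5 lists whose tests did not pass: the Polycomb, p53 target, Notch, ribosomal protein and sex-linked lists.

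Of 88 tests of a list in a direction, 19 had an adjusted p below 0.05, 11 for higher and 8 for lower calls. Genes of a list are not independent replicates, and the lists share members, so these tests describe the 4 libraries. The number of higher genes fell from 2106 to 1153 when a difference of at least 2-fold was also asked for.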

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

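Krt13 and Krt4 had high values in Tomato-positive cells but were left outside the authors' test. Krt13 was listed at 15058 FPKM and Krt4 at 4320 FPKM in Tomato-positive cells, and both at 0 in Tomato-negative cells, with a status of too many fragments. They were the only 2 genes listed at 0 in 1 fraction and at 1000 FPKM or more in the other, among 197 genes at that level in either fraction. A value of 0 with that status does not show absence of the transcript, so no difference between the fractions is shown and no fold is given.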

How the results depend on the processing

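The choice of 1 gene row per symbol and the removal of other cell type markers were added after the data were seen. Without those markers 2086 higher and 2254 lower genes were left. Only the listed markers were taken out, so this does not measure how many other calls come from RNA of other cells. Higher genes numbered 1153 when at least 2-fold was asked for and 1093 when folds were also centred, against 2106, since both add a criterion. Across the other alternatives, counts ran from 1487 to 2581 higher and from 1666 to 2723 lower genes, and lower genes numbered 1569 and 1632 under the fold criteria, all within 1.5 times the main counts. Gene list tests with adjusted p below 0.05 numbered 19, and 20 or 21 under the alternatives. Hox genes passed under both, and Langerhans cell markers with 2-fold calls. The Bmi1 log2 fold was 0.97 with pseudocount 1 and 1.13 centred. Among 628 genes of the lists and the naming rule above 0 FPKM in both fractions, none of the 352 called genes changed sign. A pseudocount cannot change a sign, and centring took only 0.045 from each log2 fold. For called genes this outcome was therefore nearly fixed in advance. Of 276 genes not called, 7 changed sign when centred. List medians moved beyond their interval for 9 of 44 lists with pseudocount 0.1 and for 0 when centred. No paired analysis was possible because the values are given per fraction, not per sample. For the same reason leave-one-out and the pseudocount on sample values were not run. Depth is unknown, so low values cannot be told from absence.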

Other observations

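All tests in this part were chosen after the results were seen, and so were the genes named as family examples. All 18 late cornified envelope genes tested fell, with Fisher's exact adjusted p = 2.12e-14 over the 18 families, for example Lce1m from 189 to 17.2 FPKM and Lce1c from 817 to 107 FPKM. In the neighbouring Sprr2 group 8 of 11 genes rose, with Fisher's exact adjusted p = 8.68e-05, Sprr2f from 22.7 to 163 FPKM and Sprr2e from 15.9 to 91.0 FPKM. The others were listed lower without passing: Sprr2a2 (1626 and 1040 FPKM), Sprr2a3 (700 and 464 FPKM) and Sprr2a1 (230 and 152 FPKM). Reads of these paralogs can be shared. Integrin genes rose in 11 of 21 and fell in 4 (Itgb7, Itgae, Itga2b and Itgbl1, the last an integrin-like gene), with Fisher's exact adjusted p = 0.000112 for higher calls, Itga3 from 7.32 to 38.9 FPKM and Itga2 from 0.336 to 3.31 FPKM. Collagens rose in 8 of 24 and fell in 7, with Fisher's exact adjusted p = 0.0247 for higher calls. The basement membrane genes Col4a1 (4.34 to 23.2 FPKM), Col7a1 (9.45 to 39.2 FPKM) and Col18a1 (6.13 to 46.2 FPKM) rose, and the fibrillar Col1a2 fell from 28.9 to 5.44 FPKM. In the same comparison fibroblast and pericyte markers fell in 14 of 16 (median -1.13), and endothelial markers were higher in 5 of 12 and lower in 1 (median 0.54). The median of the collagen family, -0.06, had the opposite sign to that test, and its symbols take in Col4a3bp, a lipid transfer protein gene that was not called. The families were picked on these values, so their p-values are not independent evidence.

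Metabolic and interferon-linked families had more lower than higher genes. In the same comparison simple epithelial and gland genes fell in 10 of 13 members and rose in 1 (median -2.50). Muc5b, Cldn3 and Cldn10 of the mucin and claudin families stand in that list too. Whether the family falls and the fall of gland genes are linked was not tested. Cytochrome P450 genes were lower in 19 of 33 and higher in 4 (Cyp7b1, Cyp4f18, Cyp4a10 and Cyp4a14), with Fisher's exact adjusted p = 1.63e-07, among them Cyp2f2 from 222 to 14.9 FPKM and Cyp2s1 from 130.3 to 22.5 FPKM. Glutathione S-transferases were lower in 10 of 18 and higher in 1 (Gsta1), with Fisher's exact adjusted p = 0.000262, among them Gstt1 from 12.9 to 1.61 FPKM and Gstp1 from 701 to 242 FPKM. Serpin clade B genes were lower in 11 of 19 and higher in 2 (Serpinb6a and Serpinb6c), with Fisher's exact adjusted p = 8.92e-05. Guanylate-binding proteins were lower in 9 of 10 and higher in 0, with Fisher's exact adjusted p = 2.58e-06. Claudins (5 of 11 lower, Cldn8 higher), UDP-glucuronosyltransferases (4 of 6 lower, 0 higher) and mucins (4 of 5 lower, 0 higher) had more falls than other genes, with Fisher's exact adjusted p = 0.0311, 0.0147 and 0.00739. Tubulins rose in 6 of 12 and fell in 2 (Tuba8 and Tubb4a), and kinesins rose in 11 of 33 and fell in 3 (Kif21a, Kifc3 and Kif9), each with Fisher's exact adjusted p = 0.00747 for higher calls. Of 63 histone genes 10 rose and 0 fell, fewer falls than among other genes, with Fisher's exact adjusted p = 0.000414. Proteasome subunits rose in 0 of 37 and fell in 4 (Psmb8, Psmb9, Psmb10 and Psmd7), with Fisher's exact adjusted p = 0.0301 for the few higher calls. The laminin, ephrin and Eph receptor, and desmosomal cadherin families did not pass.

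Inflammatory cytokine transcripts were higher in Tomato-positive cells. More leukocytes of every kind are argued against by the macrophage and dendritic cell markers. Their median log2 of (FPKM + 1) was -0.75, with the upper bound of its interval at -0.02. That list was picked after its median was seen, and the interval resamples genes, not samples. Pan-leukocyte markers, 2 higher and 3 lower of 10, had a median of -0.33 (interval -0.89 to 0.42), which does not decide. Neutrophil RNA remains open. The 5 neutrophil markers outside the alarmin list had a median of 0.66, at percentile 97.1 of random lists, short of the upper bound set. Of these, Csf3r (0.637 to 17.1 FPKM), Retnlg (0.856 to 19.2 FPKM) and Cxcr2 (3.13 to 5.51 FPKM) rose. Il1r2 fell from 180.3 to 43.6 FPKM, and Camp did not pass. The full list had a median of 2.35 (interval -0.25 to 3.47), at percentile 100. Trem1, Hdc and all 5 tested erythroid markers rose as well. Missing the bound therefore does not argue against neutrophil RNA. The most abundant markers of the full list, S100a8 (6383 FPKM) and S100a9 (4506 FPKM), also stand in the alarmin list and are made by keratinocytes, and the EpCAM sort selects against neutrophils without showing that none passed. Expression by the Bmi1-marked epithelial cells themselves was not tested and stays open.

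Interferon response transcripts were lower in Tomato-positive cells. A fall of every kind of leukocyte alike is argued against by the list medians. The median was -0.33 for pan-leukocyte markers (interval -0.89 to 0.42) and -2.23 for interferon genes (interval -2.62 to -1.88). Pan-leukocyte markers lay above interferon genes by a mean of 1.82 on the log2 scale. The two-sided permutation p was 1e-05, the smallest that 100000 permutations can give. This contrast and the next were picked after the medians were seen and permute genes, so their p-values are not independent evidence. For fewer macrophages, dendritic or Langerhans cells the difference was 1.26 with permutation p = 0.00056, but 4 of the 21 markers were called lower and fell as far as the bulk of interferon genes, so this cannot be told apart from a change in the epithelial cells. Fewer T, NK, B or mast cells, which the EpCAM sort of both fractions selects against as it does macrophages, were not tested and stay open, since T and NK cell markers (median -1.25, interval -1.58 to -0.92) and mast cell markers (median -1.25) lay lower and Igj fell, and neutrophils also express pan-leukocyte genes. A lower interferon response in Bmi1-marked cells stays open as a hypothesis and was not tested.

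Fibroblast and muscle transcripts were lower in Tomato-positive cells. A lower share of every non-epithelial cell type is argued against by the endothelial markers. Their median was 0.54, with an interval of 0.15 to 0.89. Of these 12 markers 5 were higher and 1 lower. The list itself did not pass, with an adjusted p of 0.057 by Fisher's exact test. These markers lay above fibroblast markers by a mean of 1.87 on the log2 scale, with a two-sided permutation p of 2e-05. That contrast was picked after both medians were seen and permutes genes, so its p is not independent evidence. A lower share of fibroblasts and muscle alone, Dcn falling from 406 to 58.5 FPKM, stays open and was not tested, although the EpCAM sort of both fractions selects against these cells.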
